A study of Arabidopsis thaliana with 12 samples.

How the data were processed

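RNA was sequenced from root tissue of 7-day-old Arabidopsis thaliana Col-0 seedlings in 12 libraries. Per the labels, seedlings were treated for 1 h with 50 µM CNQX, an antagonist of animal ionotropic glutamate receptors, or with a mock solution. About 130 µm of the root tip was then excised, and the plants were moved to new plates. About 100 µm of root above the wound was collected after 30 min, 4 h, 14 h or 24 h, with 1 library per treatment and time. Uncut plants stayed 14 h on CNQX or mock plates, and about 100 µm of their root tip was collected in 2 libraries per treatment. The series description names 16 h where the sample labels name 24 h as the latest time; the sample labels were followed. Whether CNQX was present in the plates after excision is not stated in the sources used here.

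The deposited values are raw counts per locus, with no normalization, for 32833 loci in each of the 12 libraries, and the deposited joint table of counts held the same number at every locus. The authors' notes name HISAT2, DESeq2 and the TAIR10 build; versions, the counting tool, its strand setting and the trimming are not given in the sources used here. Gene names and types came from the TAIR10.1 annotation, which matched 32548 of the loci; no coordinates were used. Total counts ran from 1575446 to 3302325 per library, so that 3 counts, the floor used here, stood for 0.909 to 1.90 CPM (counts scaled to library size).

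Counts were fitted in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, which left 16820 genes. Libraries were scaled by TMM, and a quasi-likelihood F test was run on all 12 libraries at once. The design held the stage (uncut or one of the 4 times), the CNQX effect in uncut roots and the CNQX effect in cut roots, which left 5 residual degrees of freedom for 7 coefficients. The CNQX effect in cut roots was the mean over the 4 times of CNQX minus mock, each within its time; its variation between times counted as spread. Excision was tested as the mean of the 4 times minus uncut, and each time was also tested against uncut, with both treatments averaged. A separate fit with 8 coefficients and 4 residual degrees of freedom split the CNQX effect in cut roots into early (30 min and 4 h) and late (14 h and 24 h) parts. P values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Values given after ± are standard errors, computed as the size of the log2 fold change over the square root of F.

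Choices up to this point, the gene lists and the rule for naming genes were made before the data were examined. The 21 lists were 15 of function and 6 of cell type markers, with 341 entries: salicylic acid defence, pattern-triggered immunity, calcium and touch immediate-early genes, jasmonate, ethylene, wound regeneration factors, auxin response, auxin synthesis, cytokinin response, G2/M cell cycle, S-phase and DNA replication, glutamate receptor-like, xenobiotic detoxification, hypoxia response, heat shock, quiescent centre and stem cell niche, root cap and columella, endodermis Casparian strip, epidermis and root hair, xylem and phloem, and photosynthetic tissue. LBD16 and LBD29 stood in both the wound and the auxin response lists. Lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01, adjusted by Benjamini-Hochberg over 105 tests, with an estimated correlation and with fry beside it. A call lost with an estimated correlation does not by itself show that members varied together. Some lists lost it with an estimate under 0.01, as pattern-triggered immunity did for CNQX in uncut roots (-0.042). The 84 list tests of single times and those of the early and late CNQX effects were added after seeing the data, each as a family of its own. Camera compares a list with all other genes, so its direction can differ from the sign of the list's median. Fry tests the members of a list without that comparison. Counts of members that passed are given over all genes and adjusted over the list alone.

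Genes were named by a fixed rule. For excision and for each CNQX comparison, it took the 8 highest and 8 lowest log2 fold changes among genes with an adjusted p under 0.05, an average log2 CPM of at least 2 and the same direction in every pair. Where fewer passed, it was filled by the lowest unadjusted p. It added up to 4 members per list and, for each time, the 3 highest and 3 lowest genes; organelle and ribosomal RNA genes were left out. List members given for single times, other than these, were those with the lowest p at that time and were chosen after their values were seen. Where a group held no count of a gene, the fold is a lower bound against 3 counts over the group. With 1 to 3 counts the ratio is given with its 95% exact Poisson interval. Intervals and floors cover counting error only. The CNQX libraries were also compared with mock at each single time by log2 ratios, with no test, and each list's median was ranked among 10000 random lists matched on expression.

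Alternatives were edgeR with RLE size factors, library size only, DESeq2 1.42.0, limma-voom, no expression filter, a filter of 5 CPM in 4 libraries, robust dispersion, organelle loci left out, the replicate number as a block, the 4 uncut or the 8 cut libraries alone, and each uncut library or each time left out. Ribosomal RNA loci left out, and the mock 24 h library left out, were added after seeing the data. The expression filter was run anew for each fit with libraries left out, which changed the members tested, so list medians from such fits are given over the members tested in both unless stated. Library size alone moved the median of all genes to -0.12 (log2) for the CNQX effect in cut minus uncut roots, to -0.14 at 24 h against uncut and to 0.17 for CNQX early minus late. The stricter filter moved it to -0.12 at 24 h. The signs of the 67 list medians called were the same under TMM, RLE and library size alone. The method was tested on simulated data with these designs. With 4-fold changes planted, 20.9% were recovered for CNQX in uncut roots, 64.2% for CNQX in cut roots and 91.0% for excision; with 2-fold changes, 0%, 9.0% and 13.4% were. Of the unchanged genes, 3, 8 and 12 were called. With nothing planted, camera called 0 of 21 lists. With the jasmonate list alone shifted 2-fold it called 3, so that 2 lists with no planted change were called. Genes were simulated independently of each other, so this does not test list calls where members vary together. In the data G2/M genes had an estimated correlation of 0.709 for CNQX in cut roots.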

Results

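The study measured RNA in Arabidopsis roots that regenerate after root tip excision, with and without the glutamate receptor antagonist CNQX. There were 4 uncut root tip libraries, 2 per treatment, and 8 libraries of tissue above the wound, 1 per treatment at 30 min, 4 h, 14 h and 24 h. Total counts ran from 1575446 to 3302325 per library, with a median of 2122122. Mitochondrial loci held 8.13% to 17.62% of counts and plastid loci 0.281% to 0.730%. The mock 24 h library stood apart from the other 11. Its ribosomal RNA loci held 1.75% of counts, against 5.32% to 10.2% in the others, and its reads not aligned uniquely were 37.6% of reads, against 53.3% to 65.3%. Its correlation across genes with the mean of the other libraries was 0.634, where the others had 0.832 to 0.948. Heat shock genes differed between uncut replicates: the list median of replicate 1 lay 1.58 (log2) above replicate 2 in mock and 1.83 above it in CNQX. P values measure only the spread between these libraries, since the labels do not say whether replicates were separate cultures.

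The comparison of cut with uncut roots asks which genes change after excision. Uncut tissue was the tip itself and cut tissue lay above the removed tip, so excision and position along the root were confounded. Of 20 jasmonate genes 8 rose and 0 fell, and of 15 wound regeneration factors 8 rose and 1 fell (list adjusted p = 0.54 and 0.491 with an estimated correlation). RAP2.6 (AT1G43160), a wound-inducible transcription factor, rose by 5.82 ± 0.65 (log2; 8 cut against 4 uncut libraries; adjusted p = 0.000227), and the jasmonate-induced repressor gene JAZ1 (AT1G19180) rose by 2.23 ± 0.27 (adjusted p = 0.000418). Of 23 G2/M genes 18 fell, of 11 stem cell niche genes 5 and of 8 root cap genes 4 (list adjusted p = 0.499, 0.491 and 0.491 with an estimated correlation). The mitotic activator gene CDC20.2 (AT4G33260) fell by 3.41 ± 0.44 (adjusted p = 0.000552), the niche factor gene PLT1 (AT3G20840) fell by 5.85 ± 0.91 and the root cap identity gene SMB (AT1G79580) fell by 6.19 ± 0.86.

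In edgeR, 4282 of 16820 genes changed after excision, 2288 up and 1994 down, and 3492 of these changed more than 2-fold. DESeq2 called 4403 and limma-voom 5387. Fallen genes outnumbered risen ones with the stricter filter (2034 up, 2257 down), with organelle loci left out (2148 and 2347) and without the 4 h libraries (2448 and 2583). The count was 2542 without replicate 1 of CNQX uncut, and without the 14 h libraries it was 2648. Among the highest risers were the defensin-like gene LCR69 (AT2G02100), at 7.57 ± 0.72, and the glutathione transferase gene ERD9 (AT1G10370), at 7.28 ± 0.49. The microRNA gene MIR163 (AT1G66725) was at least 82.1-fold higher, NAC048 (AT3G04420) at least 37.5-fold, AT4G18630 at least 33.4-fold and DOT1 (AT2G36120) at least 113-fold. The peptide precursor gene PSK5 (AT5G65870) was 240-fold higher (interval 42.8 to 9490) and the phosphate exporter gene PHO1 (AT3G23430) 142-fold (39 to 1170). The lowest were ATGSTF13 (AT3G62760), at -7.72 ± 0.64, AT1G50060, at -7.03 ± 0.68, ACX6 (AT1G06310), at -5.34 ± 0.78, and the asparaginase gene ASPGB1 (AT3G16150), at -5.22 ± 0.63. ATGSTF13 had no count at 4 h, 14 h and 24 h, AT1G50060 none at 30 min and 14 h, and ASPGB1 none at 14 h. Their folds are only bounded at those times (ATGSTF13 at least 36.6-fold lower at 24 h), so the sizes of these fitted averages are not reliable. AT4G27400 fell by 4.99 ± 0.71, AT3G19430 by 4.95 ± 0.45 and the root growth factor peptide gene RGF4 (AT3G30350) by 4.34 ± 0.76. RGF4 had no count at 30 min, where it was at least 14.5-fold lower, so its fitted average rests partly on a bound.

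Of the 20 jasmonate genes tested, 8 rose and 0 fell (9 and 0 adjusted over the list alone), with a median of 1.27; JAZ6 was at 4.16 ± 0.96 and JAZ12 at 1.37 ± 0.27 (camera adjusted p = 0.00724, adjusted p = 0.54 with an estimated correlation). Of 15 wound regeneration factors, 8 rose and 1 fell, the same numbers adjusted over the list alone, with a median of 1.01 (adjusted p = 0.0028, adjusted p = 0.491 with an estimated correlation). HSFB1 rose by 4.50 ± 0.49 and WOX13, which acts in tissue reconnection, by 2.68 ± 0.39; ERF114 was 103-fold higher (18.3 to 4100). Of 14 pattern-triggered immunity genes, 6 rose and 1 fell (8 and 1 adjusted over the list alone), with a median of 1.05 (adjusted p = 0.0253, adjusted p = 0.491 with an estimated correlation). The oxidase gene RBOHD rose by 3.92 ± 0.59 and WRKY18 by 2.51 ± 0.37, while WRKY53 fell by 1.5 ± 0.27. Of 15 salicylic acid defence genes, 4 rose and 1 fell, as also when adjusted over the list alone, with a median of 0.86 (adjusted p = 0.0253, adjusted p = 0.54 with an estimated correlation). The defence regulator gene PAD4 rose by 2.81 ± 0.30 and EDS5, a salicylic acid transporter gene, by 1.59 ± 0.37; CBP60G fell by 4.46 ± 1.14. Of 16 calcium and touch genes, 5 rose and 0 fell (6 and 0 adjusted over the list alone), with a median of 0.92; PHI-1 rose by 4.62 ± 0.74 and XTH22 by 2.17 ± 0.40 (adjusted p = 0.0222, adjusted p = 0.491 with an estimated correlation). Of 19 detoxification genes, 7 rose and 0 fell (8 and 0 adjusted over the list alone), with a median of 0.68; the glutathione transferase genes GSTU5 and GSTU8 rose by 4.49 ± 0.46 and 2.27 ± 0.31 (adjusted p = 0.00166, adjusted p = 0.54 with an estimated correlation).

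Among the 23 G2/M genes 18 fell (21 adjusted over the list alone) and 0 rose, with a median of -2.25 (camera adjusted p = 1.64e-14, adjusted p = 0.499 with an estimated correlation). The mitotic cyclin genes CYCB1;2 and CYCB1;1 fell by 2.8 ± 0.40 and 2.59 ± 0.43, and CYCA2;4 fell by 2.29 ± 0.35. Of 22 S-phase genes, 9 fell (10 adjusted over the list alone) and 0 rose, with a median of -0.91; CDT1B was at -2.53 ± 0.52 and the helicase gene MCM2 at -1.21 ± 0.33 (adjusted p = 0.000232, adjusted p = 0.54 with an estimated correlation). Of 8 root cap genes, 4 fell (5 adjusted over the list alone), with a median of -1.85; CEL5 fell by 2.79 ± 0.29, RCPG by 4.38 ± 0.87 and BRN1 by 4.06 ± 0.87 (adjusted p = 0.00101, adjusted p = 0.491 with an estimated correlation). Of 11 niche genes, 5 fell, as also when adjusted over the list alone, with a median of -0.32 and a mean of -1.90. MGP fell by 2.52 ± 0.47 and BBM by 4.13 ± 0.95; RGF2 was 48.0-fold lower (12.6 to 407; list adjusted p = 0.00995, adjusted p = 0.491 with an estimated correlation). Of 4 heat shock genes, 3 fell, as also when adjusted over the list alone, with a median of -1.92: HSFA2 by 3.66 ± 0.51, HSP90.1 by 2.11 ± 0.52 and HSP101 by 1.74 ± 0.35, while HSP70-4 was at -0.45 ± 0.35 (list adjusted p = 0.0122, adjusted p = 0.54 with an estimated correlation). Without replicate 1 of mock uncut or of CNQX uncut, which stood high in these genes, the heat shock list had medians of -1.42 and -1.29 and was not called (adjusted p = 0.101 and 0.087).

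The other 10 lists were not called by camera for excision. Casparian strip genes had a median of 3.81, with 3 of 8 risen (5 adjusted over the list alone): SGN3 by 1.5 ± 0.31 and ESB1 by 2.31 ± 0.50, with PER64 85.1-fold higher (29.0 to 414; list adjusted p = 0.0572). Root hair and epidermis genes had a median of 3.02, with 4 risen and 2 fallen of 8, as also when adjusted over the list alone (adjusted p = 0.792); the hair growth regulator gene RSL4 rose by 3.64 ± 0.61 and the hairless-cell fate gene WER fell by 3.86 ± 0.49. Xylem and phloem genes had a median of 1.29, with 2 of 6 risen (2 risen and 1 fallen adjusted over the list alone); the xylem protease gene XCP1 rose by 2.43 ± 0.75 (list adjusted p = 0.122). Photosynthetic genes had a median of 2.11, with 2 of 6 risen (3 adjusted over the list alone); PSBO1 rose by 2.07 ± 0.36 and LHCB1.3, which has near-identical copies, by 2.15 ± 0.64 (list adjusted p = 0.202). Of 9 ethylene genes 2 rose, as also when adjusted over the list alone, with a median of 0.85, among them the receptor gene ERS1 by 0.85 ± 0.22 (list adjusted p = 0.0573). Of 16 auxin response genes, 4 rose and 1 fell (5 and 2 adjusted over the list alone), with a median of 0.17; IAA2 rose by 1.56 ± 0.32 (list adjusted p = 0.703). Of 5 auxin synthesis genes, YUC8 rose by 2.5 ± 0.66, and TAA1 and YUC3 fell by 1.3 ± 0.33 and 2.68 ± 0.81, with the same calls adjusted over the list alone; the median was -0.53 (list adjusted p = 0.463). Of 6 cytokinin response genes, ARR9 rose by 1.57 ± 0.37 (2 rose adjusted over the list alone), with a median of 0.57 (list adjusted p = 0.338). None of 5 hypoxia genes (median 0.42; adjusted p = 0.644) and none of 5 glutamate receptor-like genes (median 0.08; adjusted p = 0.869) changed, also adjusted over the list alone.

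With an estimated correlation, camera called 0 of the 21 lists for excision, where fry called 8 in a single direction and 19 in either direction. Fry does not compare a list with other genes, and 4282 of 16820 genes changed. Its counts therefore do not set these lists apart from genes in general. Some list calls ended when libraries were left out; medians given here for such fits are over the members tested with and without those libraries. Without the 30 min libraries, jasmonate genes were at 0.60 (adjusted p = 0.35), against 1.03 for the same members with them, and calcium and touch genes at 0.68 (0.131), against 1.18. Pattern-triggered immunity genes were at 0.71 (0.198), salicylic acid genes at 0.78 (0.0596) and niche genes at -0.42 (0.0596), against 0.79, 0.92 and -0.32. Other calls ended while the median stayed within 1.5 times: without replicate 1 of mock uncut, salicylic acid at 0.73 (0.0974), calcium and touch at 1.28 (0.0662) and niche at -0.43 (0.0566), and without replicate 2 of CNQX uncut, wound factors at 0.85 (0.052). Without replicate 1 of CNQX uncut salicylic acid was at 0.64 (0.0843). Without the mock 24 h library, salicylic acid (0.73, adjusted p = 0.0519), pattern-triggered immunity (0.897, 0.0525), calcium and touch (0.85, 0.0534) and heat shock (-1.91, 0.0777) were not called, and without the 14 h libraries heat shock was not (-1.92, 0.0556). Niche genes were at -0.66 (0.0985) without replicate 2 of CNQX uncut. The pattern-triggered immunity call ended without any 1 of the 4 uncut libraries (medians 0.895 to 1.24). It also ended with the replicate number as a block (1.33, adjusted p = 0.0767). All cut libraries carry number 1, so the blocked excision contrast was taken against uncut tips at number 1. Among the genes named here, YUC3 lost its call in 7 of the 9 fits with libraries left out (highest adjusted p = 0.185), XCP1 (0.201) and LHCB1.3 (0.51) in 4, YUC8 (0.0705) in 3, and TAA1 (0.227), CBP60G (0.119), HSP90.1 (0.149) and ERS1 (0.0675) in 2. In 1 fit each, ESB1 (0.12), SGN3 (0.0503), PER64 (0.0781) and ARR9 (0.0698) lost theirs without the 14 h libraries, and RCPG (0.092) and BRN1 (0.0773) without replicate 2 of CNQX uncut.

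**Figure D1:**
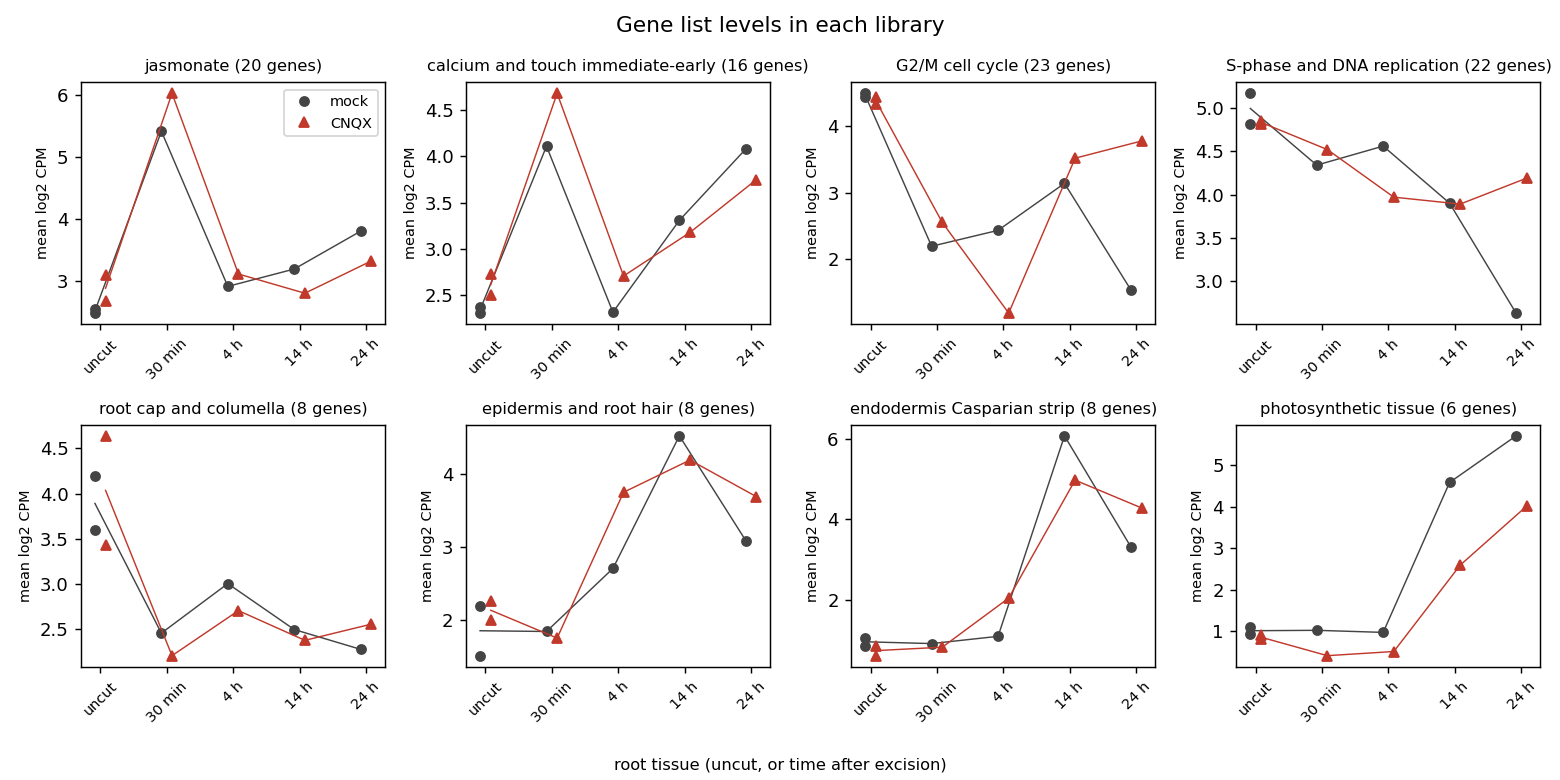
Mean log2 CPM of the genes of 8 fixed lists (y axis) in each of the 12 libraries, by stage (x axis); grey circles are mock, red triangles are CNQX, and lines join the means of each stage. Jasmonate genes stand highest at 30 min, and the mock 24 h library has the lowest S-phase level, at 2.63.

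Each time was then compared with uncut roots, both treatments together (2 against 4 libraries). At 30 min, jasmonate genes rose: 13 of 20 (19 adjusted over the list alone) and 0 fell, with a median of 3.62 (camera adjusted p = 3.22e-37, adjusted p = 0.0321 with an estimated correlation). The jasmonate response gene JAZ10 rose by 6.15 ± 0.43 (adjusted p = 2.1e-05), and the synthesis genes AOS and OPR3 rose by 3.85 ± 0.39 and 3.27 ± 0.29. Calcium and touch genes rose (8 of 16, 10 adjusted over the list alone; median 2.23; adjusted p = 1.12e-10, adjusted p = 0.0321 with an estimated correlation), among them CML38 by 5.03 ± 0.80. Pattern-triggered immunity genes rose (6 up and 1 down of 14, 8 and 2 adjusted over the list alone; median 2.3; adjusted p = 1.29e-07, adjusted p = 0.0487 with an estimated correlation), among them MPK3 by 3.57 ± 0.39. These 3 were the lists called at a single time with an estimated correlation. The methyltransferase gene FAMT (AT3G44860) rose by 9.04 ± 0.91 and the aminotransferase gene TAT3 (AT2G24850) by 8.44 ± 0.56; LOX4 (AT1G72520), a lipoxygenase gene of jasmonate synthesis, was 245-fold higher (83.1 to 1190). DESeq2 did not call FAMT (adjusted p = 0.234) or LOX4 (adjusted p = 0.286). AT1G50060, AT3G15720 and RGF4 were at least 28.9-fold, 22.1-fold and 14.5-fold lower; RGF4 lost its call in 3 of the 5 fits with libraries left out (highest adjusted p = 0.0664). Salicylic acid genes had a median of 1.11 (5 of 15 risen, 8 adjusted over the list alone; adjusted p = 9.65e-08, adjusted p = 0.175 with an estimated correlation), and 6 of 23 G2/M genes fell (19 adjusted over the list alone; median -2.62; adjusted p = 1.5e-13, adjusted p = 0.301 with an estimated correlation). In all, 745 genes changed, 544 up and 201 down. The count was 408 without replicate 1 of CNQX uncut, and without the mock 24 h library it was 1224 (741 up, 483 down). Of the calls 73.0% were up, against 59.6% of the 1092 in DESeq2.

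At 4 h, 500 genes changed, 435 up and 65 down. DESeq2 called 865, with 73.8% up against 87.0% here. The count was 295 without replicate 1 of mock uncut, without replicate 1 of CNQX uncut 239, and without the mock 24 h library 827 (610 up, 217 down). In limma-voom 137 were down. Of 20 jasmonate genes, 1 rose, also adjusted over the list alone (median 0.40; adjusted p = 0.237). G2/M genes had their lowest median, -3.07, with 7 of 23 fallen (18 adjusted over the list alone; adjusted p = 6.9e-21, adjusted p = 0.247 with an estimated correlation), among them CYCB1;2 by 4.41 ± 0.78; CDC20.2 was 41.1-fold lower (11.2 to 342). Detoxification genes had a median of 1.19 (5 of 19 risen, 10 adjusted over the list alone; adjusted p = 2.23e-07, adjusted p = 0.301 with an estimated correlation), with GSTU5 up by 3.53 ± 0.52. Wound factors had a median of 1.05 (5 of 15 risen, 7 adjusted over the list alone; adjusted p = 0.000224, adjusted p = 0.244 with an estimated correlation), with RAP2.6 up by 4.24 ± 0.79. Root hair genes had a median of 2.36 (2 of 8 risen, 5 adjusted over the list alone; adjusted p = 0.00405, adjusted p = 0.301 with an estimated correlation), with RSL4 up by 4.14 ± 0.71. ERD9 rose by 7.99 ± 0.53, AT4G36430 was at least 64.1-fold higher and the trypsin inhibitor gene TI1 268-fold higher (47.1 to 10700). ATGSTF13 was at least 32.3-fold lower and WRKY41 at least 13.0-fold lower.

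At 14 h, 2639 genes changed, 2218 up and 421 down. The down count was 675 in limma-voom, 644 in DESeq2, 803 without the mock 24 h library and 235 without replicate 1 of CNQX uncut. All 8 Casparian strip genes rose, also adjusted over the list alone, with a median of 7.76, or 7.14 with genes at 0 in a group set at their bound (adjusted p = 2.79e-13, adjusted p = 0.175 with an estimated correlation). ESB1, needed for barrier formation, rose by 5.28 ± 0.57, and MYB36, a regulator of endodermal differentiation, by 4.44 ± 0.59. Wound factors had a median of 2.81 (10 of 15 risen and 0 fallen, 10 and 1 adjusted over the list alone; adjusted p = 6.36e-06, adjusted p = 0.175 with an estimated correlation), with HSFB1 up by 5.40 ± 0.56. Root hair genes had a median of 4.58 (5 up and 1 down of 8, as also adjusted over the list alone; adjusted p = 0.00224, adjusted p = 0.301 with an estimated correlation), with EXPA7 up by 7.07 ± 0.79. Photosynthetic genes had a median of 3.82, or 3.34 at the bound (4 of 6 risen, 6 adjusted over the list alone; adjusted p = 3.65e-05, adjusted p = 0.0921 with an estimated correlation), with RBCS1A up by 5.20 ± 0.69. XTH31 (AT3G44990), a cell wall enzyme gene, was at least 441-fold higher, the laccase gene LAC3 (AT2G30210) at least 327-fold and the peroxidase gene AT3G49960 at least 302-fold; ASPGB1, ATGSTF13 and AT1G50060 were at least 32.5-fold, 34.1-fold and 29.4-fold lower.

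At 24 h, 5613 genes changed, 3577 up and 2036 down; without the mock 24 h library, which stood apart, the count was 1730, with 1564 up and 166 down. All 6 photosynthetic genes rose, also adjusted over the list alone, with a median of 5.20, or 4.89 at the bound (adjusted p = 3.89e-06, adjusted p = 0.0735 with an estimated correlation), with PSBO1 up by 4.52 ± 0.42. Casparian strip genes had a median of 5.37, or 5.11 at the bound (7 of 8 risen, as also adjusted over the list alone; adjusted p = 0.000165, adjusted p = 0.33 with an estimated correlation). S-phase genes had a median of -1.43, with 8 of 22 fallen, as also adjusted over the list alone (adjusted p = 0.000108, adjusted p = 0.384 with an estimated correlation); CDT1A fell by 2.3 ± 0.51. Of 23 G2/M genes 7 fell (10 adjusted over the list alone; median -1.52; adjusted p = 2.92e-05, adjusted p = 0.515 with an estimated correlation). In the mock 24 h library the mean log2 CPM of S-phase genes was 2.63, the lowest of the 12, against 4.19 in CNQX 24 h and 4.82 to 5.17 in uncut tips. That of G2/M genes was 1.53, against 3.78 and 4.34 to 4.5, with 1.18 in CNQX 4 h. GLR3.5 was the glutamate receptor-like gene that rose at this time, by 1.97 ± 0.46 (adjusted p = 0.00642). XTH31, AT2G38380 and AT4G26220 were at least 3660-fold, 1220-fold and 1140-fold higher, and the pectin methylesterase gene PME5 (AT5G47500) and ATGSTF13 were at least 37.1-fold and 36.6-fold lower. AT5G62340 was 508-fold lower (91.0 to 20100).

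**Figure D2:**
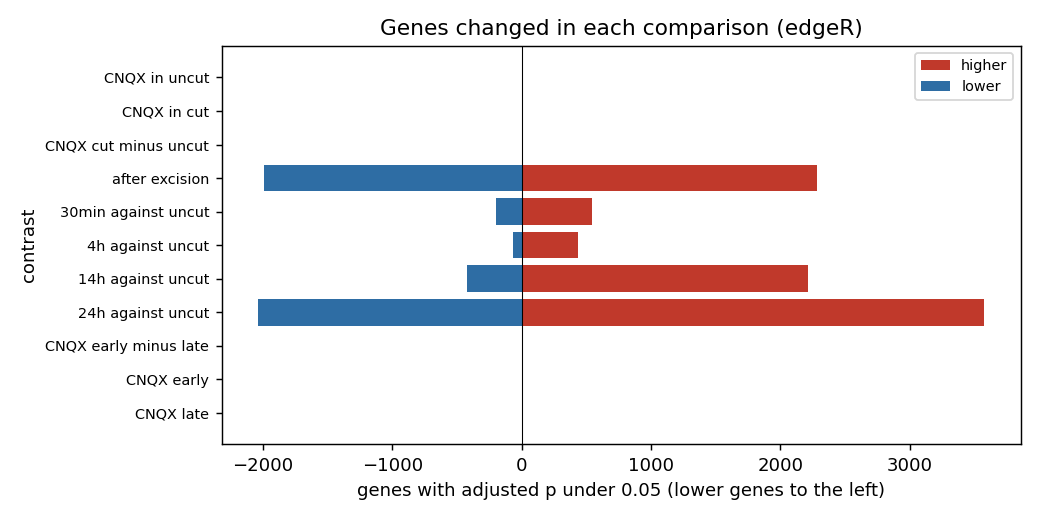
Number of genes with an adjusted p under 0.05 in edgeR (x axis; higher genes to the right, lower genes to the left) in each comparison (y axis). Bars appear for excision and for the 4 times, with 5613 genes at 24 h, and none for the CNQX comparisons.

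The comparison of CNQX with mock in uncut root tips asks what the drug does without a wound (2 against 2 libraries). Camera called 4 lists with medians above 0, while 0 genes passed. Pattern-triggered immunity genes had a median of 0.71, with 13 of 14 above 0 (camera adjusted p = 0.00282, adjusted p = 0.491 with an estimated correlation). The defence regulator gene WRKY33 was at 1.52 ± 0.50 and CYP71A12, of camalexin synthesis, at 2.21 ± 0.92. Detoxification genes had a median of 0.52, with 17 of 19 above 0 (adjusted p = 0.00282, adjusted p = 0.54 with an estimated correlation); GSTU8 was at 1.63 ± 0.47 and GSTU7 at 0.86 ± 0.38. Jasmonate genes had a median of 0.53, or 0.32 with genes at 0 in a group at their bound (18 of 20 above 0; adjusted p = 0.0253, adjusted p = 0.54 with an estimated correlation). The jasmonate catabolism gene CYP94B3 was at least 7.28-fold higher and JAZ9 at least 3.64-fold, from 14 and 7 counts in CNQX against 0, all of them in replicate 2, and AOS was at 0.96 ± 0.51. Salicylic acid genes had a median of 0.53, with 11 of 15 above 0 (adjusted p = 0.0341, adjusted p = 0.54 with an estimated correlation); NPR4, a salicylic acid receptor gene, was at 1.83 ± 0.63, or 0.645 without replicate 2 of CNQX uncut, and GRXC9 8.32-fold higher (2.38 to 44.6), with a fitted log2 value of 1.143 without that library. No member of these 4 lists passed, over all genes or adjusted over the list alone, and fry called pattern-triggered immunity alone (adjusted p = 0.0419).

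Of all genes, 0 passed in edgeR for CNQX in uncut roots (smallest adjusted p = 0.978), with 629 at an unadjusted p under 0.05 where chance gives 841. DESeq2 and limma-voom also called 0, with 481 and 636 at an unadjusted p under 0.05. In edgeR that count was 949 with the replicate block and 291 of 14182 genes in the 4 uncut libraries alone. The main fit shared its spread with the cut libraries, where change of the CNQX effect between times entered it. A count under chance therefore does not show an absence of effect in uncut tips. The lowest unadjusted p belonged to AT2G02680, at 2.29 ± 0.48 (adjusted p = 0.978, edgeR), with 27.0 ± 4.94 CPM in CNQX and 5.59 ± 1.72 in mock (mean and SD of 2 libraries). The calcium sensor gene SOS3 (AT5G24270) was at 1.98 ± 0.46, FBS3 (AT4G05010) at 1.62 ± 0.39 and the calmodulin-like gene CAM9 (AT3G51920) at 1.81 ± 0.46. KIN1 (AT5G15960), a cold-induced gene, was at least 5.72-fold higher, from 11 counts against 0, and the receptor kinase gene CRK27 (AT4G21230) was 13.0-fold higher (3.97 to 67.3). Lower in CNQX were the trehalose phosphate synthase gene TPS1 (AT1G78580), at -1.64 ± 0.46, the threonine aldolase gene THA2 (AT3G04520), at -1.59 ± 0.45, and ECIP1 (AT4G24800), at -1.36 ± 0.42; none of these passed. Each of the 4 list calls ended without replicate 2 of CNQX uncut: over the members tested with and without it, the jasmonate median was then 0 (adjusted p = 0.572), salicylic acid 0.12 (0.717), detoxification 0.23 (0.054) and pattern-triggered immunity 0.67 (0.0968). Each also ended without replicate 1 of mock uncut, with medians of 0.41 (0.313), 0.47 (0.507), 0.30 (0.457) and 0.70 (0.18). The pattern-triggered immunity call ended as well without replicate 1 of CNQX uncut (0.58, adjusted p = 0.0718), and the jasmonate call without the 30 min libraries (0.33 over 14 members, adjusted p = 0.2). The salicylic acid call ended in 6 of the 9 fits. The differences between replicates 1 and 2 had r = 0.375 between mock and CNQX. With the replicate block, jasmonate (0.51, adjusted p = 0.0927) and salicylic acid genes (0.53, adjusted p = 0.0526) were not called, while pattern-triggered immunity (0.62, adjusted p = 0.00529) and detoxification genes (0.55, adjusted p = 0.00422) were.

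Within cut roots, CNQX was compared with mock over the 4 times, the comparison closest to the study's question of what the drug does to regenerating roots. Photosynthetic genes stood lower in CNQX, with a median of -1.93 and 0 of 6 above 0 (camera adjusted p = 1.23e-09, adjusted p = 0.458 with an estimated correlation). Adjusted over the list alone 4 of 6 fell, and over all genes 0 did. The Rubisco subunit genes RBCS1A and RBCS3B were at -2.58 ± 0.57 and -2.76 ± 0.88, and the antenna genes LHCB1.3 and LHCA1 at -1.69 ± 0.55 and -2.17 ± 0.84. G2/M genes had a median of 0.48, with 19 of 23 above 0 (adjusted p = 0.00193, adjusted p = 0.681 with an estimated correlation), and S-phase genes a median of 0.42, with 17 of 22 above 0 (adjusted p = 0.0255, adjusted p = 0.663 with an estimated correlation). CDC20.1 was at 1.86 ± 0.76, CYCB1;2 at 1.21 ± 0.55 and MCM2 at 0.81 ± 0.42; no member of either list passed, also adjusted over the list alone. Both cell cycle lists moved with the mock 24 h library, which stood apart: without it their medians were 0.06 (adjusted p = 0.161) and -0.02 (adjusted p = 0.278), and camera's direction was Down for both. Without the 30 min libraries the S-phase median was 0.465, against 0.42 with them, and the list was not called (adjusted p = 0.0675). Photosynthetic genes were called with any of these libraries left out, with medians from -2.18 to -1.11, though 3 of 6 members were tested without the 24 h libraries.

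For CNQX in cut roots 0 genes passed in edgeR (smallest adjusted p = 0.772), with 327 at an unadjusted p under 0.05 where chance gives 841. DESeq2 and limma-voom called 0, with 245 and 571. Change of the effect between times counted as spread, so these counts do not show an absence of effect at single times. In the separate edgeR fit, 1669 genes had an unadjusted p under 0.05 for the late effect and 184 for the early effect. None passed (smallest adjusted p = 0.132 for the late effect). The late effect includes the mock 24 h library, which stood apart. Over the 4 times, the lowest p belonged to the cytochrome P450 gene CYP702A5 (AT4G15393), at -4.90 ± 0.76 (adjusted p = 0.772, edgeR). The peroxidase gene PRXCB (AT3G49120) was at -2.37 ± 0.44, AT3G59930 at -3.67 ± 0.67 and the glucanase-like gene AT4G16260 at -2.46 ± 0.60. CNQX was above mock at 1 of 4 times for CYP702A5 and PRXCB, at 2 for AT3G59930 and at 0 for AT4G16260. AT5G33355 was 88.6-fold lower (24.2 to 737) and AT4G11393 79.0-fold lower (21.5 to 658). Higher at 4 of 4 times were AT2G45180, at 1.48 ± 0.34, the malate synthase gene MLS (AT5G03860), at 1.28 ± 0.40, RIP4 (AT1G78430), at 2.48 ± 0.76, and the cellulase gene CEL3 (AT1G71380), at 2.16 ± 0.71. Without an expression filter 10 genes passed, 1 up and 9 down, among them CYP702A5 (adjusted p = 9.25e-09) and RBCS1A (0.00574). Their log2 values were then -4.91 and -2.57, nearly the same as with the filter. The effects were thus not larger, and these calls rest on how the spread was fitted. The 5 glutamate receptor-like genes tested ranged around a median of -0.47 and none passed; GLR3.3 was at -0.47 ± 0.31. The jasmonate list stood near 0, with a median of 0.01, a mean of -0.02 and a camera direction of Down; hypoxia genes had a median of 0.10 and a mean of -0.19, niche genes -0.12 and 0.31, and Casparian strip genes -0.02 and 0.15, none of them called.

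The test of whether the CNQX effect differed between cut and uncut roots called 0 genes in edgeR, DESeq2 and limma-voom, with 390, 314 and 471 at an unadjusted p under 0.05 where chance gives 841. Change of the CNQX effect between times entered the spread here too, so these counts do not show an absence of difference. Cut plants had 1 h of CNQX before excision, with later exposure not stated, where uncut plants had 14 h. Tissue position differed as well, so a difference cannot be ascribed to the wound alone. As groups, jasmonate genes had a cut minus uncut difference of -0.47, or -0.36 at the bound (3 of 20 above 0; camera adjusted p = 0.0493, adjusted p = 0.54 with an estimated correlation). Detoxification genes had a median of -0.51 (3 of 19 above 0; adjusted p = 0.024, adjusted p = 0.643 with an estimated correlation), with GSTU8 at -1.88 ± 0.56. G2/M genes had a median of 0.64 (19 of 23 above 0; adjusted p = 0.00724, adjusted p = 0.757 with an estimated correlation), with CYCB1;2 at 1.95 ± 0.83. S-phase genes had a median of 0.52 (18 of 22 above 0; adjusted p = 0.0222, adjusted p = 0.651 with an estimated correlation), with MCM4 at 1.78 ± 0.73. No member of the 4 lists passed, also adjusted over the list alone. The lowest p belonged to CYP702A5, at -6.16 ± 1.17, and AT2G02680, at -2.55 ± 0.57; among genes above 0 were EMB2016 (AT3G05680), at 1.48 ± 0.49, and the phosphatase gene ABI2 (AT5G57050) of abscisic acid signalling, at 2.83 ± 0.99. Without the mock 24 h library no list was called, and the medians were 0.20 for G2/M, 0.06 for S-phase, -0.31 for detoxification and -0.30 for jasmonate. Without replicate 1 of mock uncut no list was called either, and the detoxification median was 0.02; without replicate 2 of CNQX uncut the jasmonate median was -0.08 (adjusted p = 0.654). With the replicate block the jasmonate median was -0.47 and the list was not called (adjusted p = 0.107). Over the 4 lists and all fits with libraries left out, the call was kept in 14 cases, lost in 20 and changed direction in 2. In 3 uncalled lists the median lay above 0 where camera gave Down: glutamate receptor-like (0.004), hypoxia (0.16) and root hair (0.07). The ethylene list had a median of 0.20 and a mean of -0.12.

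The CNQX effect in cut roots was also split into early and late times, to ask whether it changed with time. All 23 G2/M genes had a lower CNQX effect early than late, with a median difference of -1.79 (camera adjusted p = 5.73e-09, adjusted p = 0.54 with an estimated correlation), and S-phase genes had a median of -1.297 (3 of 22 above 0; adjusted p = 0.000232, adjusted p = 0.54 with an estimated correlation). Niche genes had a median of -1.05 (adjusted p = 0.025, adjusted p = 0.491 with an estimated correlation), with 2 of 11 lower adjusted over the list alone. Jasmonate genes had a median of 0.90 (16 of 20 above 0; adjusted p = 0.0129, adjusted p = 0.491 with an estimated correlation). Salicylic acid genes had a median of 0.80 (adjusted p = 0.0226, adjusted p = 0.491 with an estimated correlation), and detoxification genes 0.73 (adjusted p = 0.0147, adjusted p = 0.565 with an estimated correlation). For single genes edgeR called 0, with 1203 at an unadjusted p under 0.05 where chance gives 841; DESeq2 called 3 and limma-voom 0, with 1013 and 1266. Without the mock 24 h library, the medians over shared members were -0.86 for G2/M (adjusted p = 0.000404) and -0.28 for S-phase genes (0.148). Salicylic acid was then at 0.43 (0.138), detoxification at 0.40 (0.639) and niche at -0.25 (0.115), none of them called; jasmonate was at 0.77, against 0.90 with the library, and was not called (0.0835). Without the 4 h libraries detoxification was at 0.21 (0.333), and without the 30 min libraries jasmonate was at 0.67 (0.118) and salicylic acid at 0.835 (0.17). The niche call ended in 7 of the 9 fits with libraries left out, the salicylic acid call in 4 and the jasmonate and detoxification calls in 3 each. The heat shock list, not called, had a median of -0.35 where camera gave Up.

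At each single time 1 CNQX library was compared with 1 mock library, so there was no replicate check. G2/M genes stood below mock at 4 h, by a median of -1.11 with 0 of 23 higher in CNQX, and above it at 24 h, by 2.45 with 23 of 23 higher; of 10000 random lists, 0% lay lower at 4 h and 100% at 24 h. At 14 h their median was 0.57 and at 30 min 0.20. S-phase genes followed, at -0.50 at 4 h and 1.82 at 24 h. In the mock 24 h library, which stood apart, G2/M and S-phase levels were low. Salicylic acid genes were at 0.87 at 30 min and -0.55 at 24 h, and jasmonate genes at 0.35 and -0.55. Photosynthetic genes were lower in CNQX at 14 h, by a median of -1.79, and at 24 h, by -1.61, with 0 of 6 higher at both. Casparian strip genes were at 0.93 at 4 h, -1.05 at 14 h and 0.90 at 24 h, and root hair genes at 1.12, -0.20 and 0.59. Xylem and phloem genes were at -0.84 at 24 h, with 1 of 6 higher in CNQX. At 24 h 3275 genes were more than 2-fold higher and 2405 more than 2-fold lower in CNQX, against 1002 and 842 at 30 min.

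**Figure D3:**
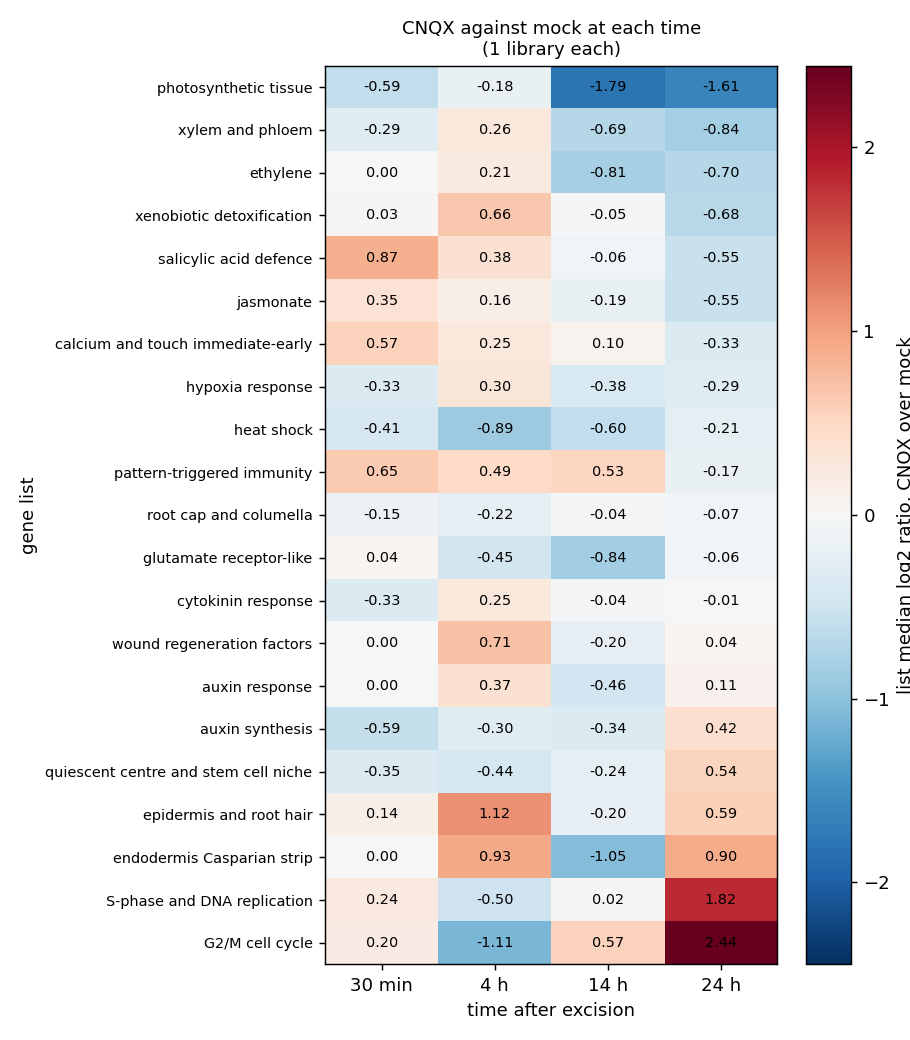
Median log2 ratio of CNQX over mock (colour and printed number) of each of the 21 lists (y axis) at each time after excision (x axis), 1 library per treatment and time. G2/M genes go from -1.11 at 4 h to 2.45 at 24 h. Photosynthetic genes are below 0 at every time, but at 30 min from 12 counts in CNQX and 16 in mock, and at 4 h from 13 and 18.

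The CNQX effects in uncut and in cut roots, which rest on different libraries, were compared across genes to ask whether the same genes responded. Pearson's r was 0.0517 and Spearman's rho 0.0595 over 16820 genes, and 52.3% had the same sign. Genes are not independent replicates, so no p is given. No gene passed for either effect, and the median standard errors (log2) were 0.57 in uncut and 0.417 in cut roots. The effect in cut roots also averaged early and late effects, which had r = -0.20 with each other. Tissue position and the stated time on CNQX differed too. A low r therefore does not show that different genes responded.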

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

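The tests on leaving out the mock 24 h library, on mature tissue, on green shoot tissue, on position along the root and on regrouped samples were chosen only after the result was seen. The results here stood out because the CNQX effect differed between cut and uncut roots, or between early and late times, in a test of the difference itself. Between cut and uncut roots the medians (log2) were -0.47 for jasmonate, 0.64 for G2/M, 0.52 for S-phase and -0.51 for detoxification genes. Between early and late times they were 0.80 for salicylic acid, 0.90 for jasmonate, -1.79 for G2/M, -1.297 for S-phase, 0.73 for detoxification and -1.05 for niche genes. With an estimated correlation none of these 10 calls passed, with adjusted p from 0.491 to 0.757. For early minus late, the estimates for salicylic acid (-0.001), jasmonate (-0.005) and niche genes (-0.065) lay under the preset 0.01. The loss of those 3 calls therefore does not show that their members varied together. Cut and uncut roots also differed in tissue position and in the stated time on CNQX.

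The first pattern is that G2/M and S-phase genes had a lower CNQX effect early than late. The mock 24 h library stood apart, so it could be the whole source. For G2/M genes it was not the only library behind the difference. Without it the early minus late median was -0.91 over the 24 genes then tested, with 20 below 0. The standard error over members, 0.242, does not measure the spread between libraries, since members varied together (estimated correlation 0.572). The late effect then rests on the 14 h pair alone (0.57). The early effect lay at 4 h (-1.11, against 0.20 at 30 min), again 1 library per treatment. For S-phase genes the mock 24 h library as the whole source stays open, since the median without it was -0.28, with a standard error of 0.231. More mature tissue in the mock 24 h library was predicted to put all 3 lists of mature cell types below 0. Xylem and phloem genes were (-0.84, standard error 0.547), but Casparian strip genes were at 0.90 with a standard error of 0.25. That prediction cannot decide, because levels of Casparian strip genes did not keep rising with time. Their mean log2 CPM went from 6.07 at 14 h to 3.31 at 24 h in mock, and from 4.97 to 4.28 in CNQX. More mature tissue in the mock 24 h library therefore stays open. Members varying together between single libraries cannot be told apart from an effect of CNQX on G2/M genes. Uncut replicates differed by -0.085 (mock) and 0.06 (CNQX), under the bound set beforehand; that bound does not decide, because cut libraries had 1 per treatment and time and the call was lost with an estimated correlation (adjusted p = 0.54).

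The second pattern is the lower level of photosynthetic genes in CNQX cut libraries, which lay mostly at 14 h and 24 h. RBCS1A was at 12.9 and 17.1 CPM in CNQX against 52.9 and 149 in mock. Too few counts cannot explain it: the ratio of summed counts was 0.291 at 14 h (116 against 469 counts) and 0.335 at 24 h (272 against 1291), and the higher of the upper 95% bounds was 0.382. Green shoot tissue in the mock libraries could also raise these genes. Plastid loci had a median CNQX minus mock of 0.13 (76 loci, standard error 0.057), but uncut roots already held 5453 CPM on these loci against 7520 in mock 24 h. A small share of shoot tissue therefore cannot be told apart from a CNQX effect. Each time had 1 library per treatment, so a difference between single samples also stays open.

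The third pattern is the change after excision, where cut tissue also came from another position along the root. For jasmonate genes position alone is argued against: 30 min minus 4 h, both taken above the wound, had a median of 2.52 with 20 of 20 genes above 0 (p = 0.000278 with an estimated correlation). For G2/M genes (30 min minus later times, camera p = 0.886 with an estimated correlation, n = 12 libraries in the fit) and root cap genes (p = 0.937) position and excision cannot be told apart, since uncut tips were the only controls.

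Regrouping the samples tested whether chance can be excluded. For excision, 40 of 495 splits of the 12 libraries were fitted. The real split called 2431 genes and the highest other 0, so that 1 of the 40 gave as many. These fits held the grouping and treatment but not the times, unlike the full design that called 4282 genes. Other groupings thus left the differences between cut and uncut roots and between times in their spread, which favours few calls. No fitted split put all late libraries in the smaller group. The splits therefore do not exclude chance by themselves. For CNQX in cut roots the splits were too few: time pairs these libraries, and 8 splits part all 4 pairs, the real one among them, so that no share can fall under 0.05. For lists the real split called 3 and the highest other 7, and 7 of the 8 gave as many. For genes both called 0, so that all 8 had to give as many and the count tests nothing. The remaining splits were left out of the count, since they part 2 pairs or none and, where fitted, rest on those 2 pairs alone.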

How the results depend on the processing

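Leaving out ribosomal RNA loci or the mock 24 h library, and medians over shared members, were chosen after seeing the data. Unless a reason is given, the cause was not tested. RLE, library size alone, limma-voom, the stricter filter, robust dispersion and organelle or ribosomal RNA loci left out kept every total of genes called within 1.5 times, though not each direction: limma-voom called 137 genes down at 4 h, against 65, and 675 at 14 h, against 421. Without an expression filter more genes were tested, and 10 passed for CNQX in uncut roots, 10 in cut roots, 2 for their difference, 35 for early minus late, 1740 at 30 min and 1421 at 4 h. In cut roots, CYP702A5 (-4.91), AT3G59930 (-3.67) and PRXCB (-2.37) passed at nearly the log2 values they had with the filter. Testing more genes does not account for those calls. DESeq2 called 865 at 4 h and 3 for early minus late. With the replicate number as a block, 1 gene (CYP702A5) and 6 lists were called for CNQX in cut roots; 2 of the 4 list calls for CNQX in uncut roots were lost. The labels do not say whether the numbers pair mock with CNQX libraries; the 2 uncut pairs' differences had r = 0.375 across 15444 loci, so pairing stays open. With an estimated correlation 0 lists were called in all 5 comparisons. In a single direction, fry called 1 for CNQX in uncut roots, 0 in cut roots, 0 for their difference and 0 for early minus late; in either direction it called 0, 1, 0 and 1, and 19 for excision. With libraries left out, where a lone remaining sample is assumed to vary like the other groups, counts ran from 2542 to 5031 for excision, 408 to 1224 at 30 min, 239 to 827 at 4 h, 2041 to 3205 at 14 h and 1730 to 5712 at 24 h. Lists called ran from 1 to 5 for CNQX in uncut roots, 2 to 6 in cut roots, 0 to 4 for their difference, 6 to 13 for excision and 3 to 6 for early minus late.

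With libraries left out, list medians (log2) over all members then tested, which the filter could change, ran as follows. CNQX in uncut roots: salicylic acid 0.04 to 0.56, pattern-triggered immunity 0.31 to 0.70, jasmonate 0 to 0.74, detoxification 0.23 to 0.84. CNQX in cut roots: G2/M 0.05 to 0.91, S-phase -0.02 to 0.78, photosynthetic -2.18 to -1.11. Cut minus uncut: jasmonate -0.72 to 0.02, G2/M 0.13 to 1.05, S-phase 0.05 to 0.78, detoxification -0.77 to 0.02. Early minus late: salicylic acid 0.42 to 0.99, jasmonate 0.67 to 1.21, G2/M -3.28 to -0.91, S-phase -2.27 to -0.28, detoxification 0.21 to 1.301, niche -1.45 to -0.20. Excision: salicylic acid 0.75 to 1.097, pattern-triggered immunity 0.71 to 1.80, calcium and touch 0.66 to 1.37, jasmonate 0.60 to 1.49, wound factors 0.78 to 2.03, heat shock -2.28 to -1.29 and niche -1.32 to -0.42; G2/M -2.57 to -1.74, S-phase -1.11 to -0.73, detoxification 0.42 to 0.93 and root cap -3.03 to -1.66 were called in each. The test changed direction for CNQX in cut roots without the 24 h libraries (medians G2/M 0.047, S-phase -0.021) and without mock 24 h (0.099, -0.016), and for the G2/M cut minus uncut difference (0.175 and 0.127). For CNQX in uncut roots, fitted values of WRKY40 ran from -0.20 to 1.755, of CYP94B3 from 0 to 6.934 and of LOX4 from 0 to 4.754, each lowest without replicate 2 of CNQX uncut. For the difference LOX4 ran from -4.268 to 0.468, highest without that library, and GSTU5 from -1.846 to 0.347, highest without replicate 1 of CNQX uncut. After excision HSP70-4 ran from -0.798 to 0.042, highest without replicate 1 of CNQX uncut. CYP94B3 and LOX4 had 0 counts in mock uncut, so their fitted values are no bounds. Depth limits low genes: 3 counts stood for 0.909 to 1.90 CPM.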

Other observations

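Late niche genes were looked at only after their values were seen; the test of a smaller late response was set beforehand. In the late CNQX effect 3 of 11 niche genes were higher adjusted over the list alone, and 0 over all genes; the list median was 0.14, with 6 of 11 above 0 (camera adjusted p = 0.0601). At 14 h the median was -0.24 with 4 of 11 higher in CNQX, and at 24 h, against the mock library that stood apart, 0.54 with 7 of 11. Those 3 were BBM, PLT2 and MGP. BBM was at 3.48 and 4.97 CPM in CNQX at 14 h and 24 h against 0 and 0 in mock, PLT2 at 3.98 and 5.52 against 0.42 and 0, and MGP at 6.97 and 2.76 against 0.85 and 0.69. In these libraries 3 counts stood for 0.987 (mock 24 h) to 1.45 CPM (CNQX 24 h). All the mock values lay under that floor, and the differences rest on few counts in single libraries.

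Uncut replicates differed in other lists than heat shock: replicate 1 minus 2 was -0.84 in mock and -0.84 in CNQX for root cap genes, -0.67 and -0.71 for auxin synthesis genes, and -1.04 and -0.36 for xylem and phloem genes.

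A hypothesis is that the late response to excision may be smaller in CNQX. Genes were called at one late time and read at the other, without the libraries in which they were read. The 2887 genes risen at 24 h had a CNQX minus mock median of -0.47 at 14 h, and the 1852 fallen genes 0.33. The 2119 genes risen at 14 h had -0.45 at 24 h, and the 735 fallen genes 1.24. Both readings use the mock 24 h library, which stood apart, either to call the genes or to read them. The value least to the predicted side was 0.33, past the bound of 0.2 set beforehand. Genes risen and fallen after excision, lists taken from these data, went the other way in the early CNQX effect, with medians of 0.25 and -0.25. In the late effect they had -0.40 and 0.67, and neither list passed in camera with an estimated correlation (adjusted p = 0.317 for both). Each time had 1 library per treatment, so a library that had advanced less is not separated from an effect of CNQX.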
